A study of Mus musculus with 64 samples.

How the data were processed

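RNA was measured by sequencing of total RNA in 64 libraries of cultured mouse CD4 T cells, with 4 libraries in each of 16 groups formed by 4 genotypes and 4 times of restimulation. Per the labels' protocols, RNA was extracted with Trizol and libraries were prepared with a NuGEN kit. Per the submitters' processing notes, the genome build was GRCm38. The aligner, the counting tool, the annotation and the strand setting used by the authors are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands could not be told apart. Such an overlap is noted beside some of the genes named. Ccna2, Pax5, Cnot3, Klf3, Il21, Ebi3, Sh2d1a, Trpc5, Clnk, Trp73, Bicd1, Ermn, Ikzf4, Mb21d1, Il2, Amica1, Csf2, Pou2f2, Hrh2, Irf1, Hk2, Gata3 and Tcf7 also overlap a gene on the opposite strand, which had at most 27.3% as many reads (Exosc9 for Ccna2).

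Per the file headers, the authors deposited 1 table of 23134 genes that holds, for each group, a list of 4 normalized read counts. The lists carry no replicate numbers, so a library is named here by its group and its place in the list, and that number pairs it with no other library. The deposited group means (signal, in normalized counts) differed from the means of the listed values by at most 0.049%, and were not used further. Per the file headers, the authors also deposited a false discovery rate (a p-value adjusted by them) and a log2 fold change for each of 19 comparisons. These were used only to count how many of the authors' calls were shared. In every library the low values were whole multiples of 1 step. With a tolerance of 0.1 read, 100% of the low values gave whole reads, and the recovered totals were 5369873 to 11666603 reads per library (median 7720297). The 10 most abundant loci, led by the long noncoding RNAs Gm26924 and Gm26561, held 26.65 to 38.11% of a library's reads. The chi-square statistic between libraries of a group was 4.52 to 60.13 per degree of freedom, so no pair differed by as little as sampling noise and each was counted separately.

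The design, the alternatives and the gene lists were chosen before the data were examined. That design foresaw a count model. Because the deposited values are lists of normalized counts, the test used was limma on log2(value + 1), the option foreseen for such values. Values were rescaled with factors from the trimmed mean of M values (TMM, trims of 30 and 5 percent) over the genes kept. Genes were kept if at least 10 reads at the median depth, which is 1.3 CPM (counts per 1e6 reads), were reached in at least 4 libraries and their reads summed to at least 15, which left 16140 genes. The model had 1 mean per group over all 64 libraries (48 residual degrees of freedom), with trended and robust empirical Bayes moderation. The median residual SD was 0.328 on the log2 scale. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over all genes tested in a contrast. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and are given ± SE with n = 4 libraries per group. Where a group had 1 to 3 reads in all, the ratio of CPM is given with a 95% exact binomial interval, which covers counting error only. The labels do not say that the 4 libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

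The contrasts were each restimulation time against 0 h in control cells, each genotype against control cells at each time, the triple knockout against the other knockouts at 0 and 4 h, non-additivity (the triple-knockout effect minus the sum of the Roquin and Regnase-1 effects) at 0 and 4 h, and the difference between a knockout and control cells in the change from 0 to 4 h. Gene lists were tested with limma camera at its preset correlation and again with an estimated correlation, adjusted over 600 tests. The 28 lists covered known Roquin or Regnase-1 target mRNAs, Th1, Th2, Th17, Tfh and Treg genes, naive T cell genes, cytotoxic effectors, immediate early genes, cytokines and chemokines, the NF-kB pathway, inhibitory receptors, costimulatory receptors, glycolysis, the cell cycle, interferon-stimulated genes, cholesterol synthesis, RNA-binding and mRNA decay factors, ribosomal proteins, mitochondrially encoded genes, heat shock genes, and markers of CD8 T, B, myeloid, NK, neutrophil, erythroid or platelet, and dendritic cells. Of these, 166 tests passed at the preset correlation and 14 with an estimated correlation. For a list, counts of called members are given over all genes tested and adjusted over the list alone. Levels of the 3 targeted genes were compared by exact 2-sided permutation tests over 70 arrangements of 4 against 4 libraries, whose smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over 36 tests.

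The genes named were set by rule. The 3 targeted genes were always named. A gene was eligible at an adjusted p under 0.05, a mean log2 CPM of at least 1 over the groups compared and, for contrasts of 2 groups, all 4 libraries of 1 group above all 4 of the other. The 8 eligible genes with the largest rise and the 6 with the largest fall were taken for the triple knockout against control cells at 0 and 4 h, and 4 and 3 for the other contrasts. Some of these whose call an alternative ended are left out. For each list, up to 4 called members with the smallest adjusted p and every called known target were added. Unnamed predicted genes, pseudogenes and receptor segments were skipped. Clone names and names ending in -ps were read as such after the first listing had been seen, for all contrasts alike. Symbols and identifiers are as deposited, and 90 symbols are shared by more than 1 entry. Coordinates are from the GENCODE vM21 annotation of GRCm38, which held 22724 of the 23134 identifiers.

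Alternatives were median-of-ratios scaling, no filter, a filter at 5 CPM, a filter at a mean value of 1, pseudocounts of 0.1 and 5, a fit on only the groups compared, and each library left out in turn. Chosen after seeing the data were the deposited scaling, TMM over all genes, TMM over genes of at least 5 CPM, limma voom on the recovered reads, leaving out the library of each group with the highest share of its reads in the 10 top loci, and, for contrasts within a time or between responses, a block of library sets. A set holds 1 library per genotype at a time, found by correlation in the same data, so this fit is not independent of them. Scaling by total reads was also looked at. The scaling mattered. With TMM over the genes kept, the median log2 change of genes of at least 5 CPM was 0.27 for Regnase-1 loss at 4 h, 0.26 for triple loss at 4 h, 0.26 for the difference in response with Regnase-1 loss, 0.14 for triple loss at 0 h, 0.14 and 0.11 for the triple knockout against the Roquin knockout at 4 and 0 h, 0.13 for the triple against the Regnase-1 knockout at 0 h, 0.11 for Roquin loss at 4 h, 0.11 for the difference in response with triple loss, and -0.12 for non-additivity at 4 h, and it lay within 0.10 of 0 in the other contrasts. Counts of genes called in the same direction under all 5 scalings are therefore given first, and changes of under about 0.5 on the log2 scale in these contrasts are left out or given relative to the shift.

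A simulation with few changed genes was built for the triple knockout against control cells at 4 h. The test found 41.8% of 67 genes changed 1.5-fold, 94.0% of 67 changed 2-fold and 100% of 66 changed 4-fold. Of its calls 6.5% were false. Real rates may differ. The analysis used R 4.3.3, limma 3.58.1, statmod 1.5.0 and the package data.table at version 1.17.8, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.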

Results

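Transcripts were measured in splenic CD4 T cells of C57BL/6J mice whose Cre recombinase, made in Cd4-expressing cells, had been switched on with 4-OH-tamoxifen to delete floxed genes. Roquin-1 and Roquin-2, encoded by Rc3h1 and Rc3h2, and Regnase-1, encoded by Zc3h12a, are RNA-binding proteins known to repress mRNAs of T cell activation. Control cells (WT) carried Cre alone. The other genotypes lacked both Roquin genes (DKO), Zc3h12a (KO) or all 3 genes (TKO). The cells had been activated under Th1 conditions, rested in medium with IL-2, and then left without restimulation (0 h) or restimulated through CD3 and CD28 for 1, 2 or 4 h. Each of the 16 groups held 4 libraries, 64 in all. The series title names an interaction and cooperation of Roquin-1 and Regnase-1, and the comparisons ask what each loss and the combined loss did to transcripts before and during restimulation. Unless another test is named, adjusted p values are from limma with Benjamini-Hochberg adjustment over 16140 genes. Changes are log2 ± SE, and levels are normalized values or CPM as mean ± SD. Each has n = 4 libraries per group. Genes named for the size of their change between 2 groups had all 4 libraries of one group above all 4 of the other.

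Zc3h12a rose with restimulation in control cells, and at 1 h it was lower in each library labelled as lacking it than in any control library. In WT cells it stood at 10.4 ± 1.1, 113.7 ± 14.8, 86.1 ± 32.8 and 18.1 ± 3.2 CPM at 0, 1, 2 and 4 h. At 1 h it was 69.7 ± 14.2 CPM in KO cells (exact permutation p = 0.0286) and 59.7 ± 4.7 in TKO cells (exact p = 0.0286). At 2 h it was 53.3 ± 7.7 in KO cells (exact p = 0.0857) and 47.5 ± 4.8 in TKO cells (exact p = 0.0286). At 0 h KO cells held 13.3 ± 3.3 and TKO cells 16.1 ± 4.7 CPM (exact p = 0.1714 and 0.0571). At 4 h they held 16.5 ± 4.7 and 15.8 ± 1.3 (exact p = 0.5143 and 0.2286). In DKO cells, where Zc3h12a is intact, it was 35.8 ± 2.8 CPM at 0 h and 40.8 ± 6.1 at 4 h, above every WT library (exact p = 0.0286 at each time). At 1 and 2 h it was 146.2 ± 21.5 and 130.5 ± 30.0 (exact p = 0.0571 and 0.1143). Rc3h1 in WT cells was 79.1 ± 10.6, 102.7 ± 6.6, 154.3 ± 20 and 151.2 ± 8.2 CPM over the 4 times. In DKO cells it was 63.1 ± 7.6 at 0 h (exact p = 0.0571) and 68.4 ± 3.9, 84.0 ± 4.8 and 67.2 ± 2.6 later (exact p = 0.0286 at each time). TKO cells held 70.3 ± 8.4 at 0 h (exact p = 0.2571) and 71.1 ± 6.2, 86.0 ± 6.1 and 76.8 ± 7.7 later (exact p = 0.0286 at each time). KO cells held 83.0 ± 8.5, 103.7 ± 11.5, 172.0 ± 6.8 and 172.8 ± 23.4 CPM of Rc3h1.

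The mean of Rc3h2 was below that of WT cells in no knockout group. It was 67.4 ± 5.7 CPM in WT cells at 0 h, against 87.2 ± 7.5 in DKO cells and 98.0 ± 13.0 in TKO cells (exact p = 0.0286 for each). KO cells held 78.4 ± 6.1 (exact p = 0.0571). At 1 h the means were 81.3 ± 12.4 in WT, 102.3 ± 5.9 in DKO and 114.0 ± 11.9 in TKO cells (exact p = 0.0286 for each). At 4 h they were 69.6 ± 12.2 in WT, 80.4 ± 9.2 in DKO (exact p = 0.1429) and 100.6 ± 15.1 in TKO cells (exact p = 0.0571). The smallest p that 4 against 4 libraries can give is 0.0286, which became 0.0686 after adjustment over the 36 tests of the 3 genes. The floxed exons are not given in the sources used here and the values cover whole genes, so they check the deletions only in part. In the GRCm38 annotation Rc3h1 is ENSMUSG00000040423, chromosome 1, 160906418 to 160974978, plus strand. Rc3h2 is ENSMUSG00000075376, chromosome 2, 37370069 to 37422903, minus strand. Zc3h12a is ENSMUSG00000042677, chromosome 4, 125118423 to 125127840, minus strand.

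**Figure D1:**
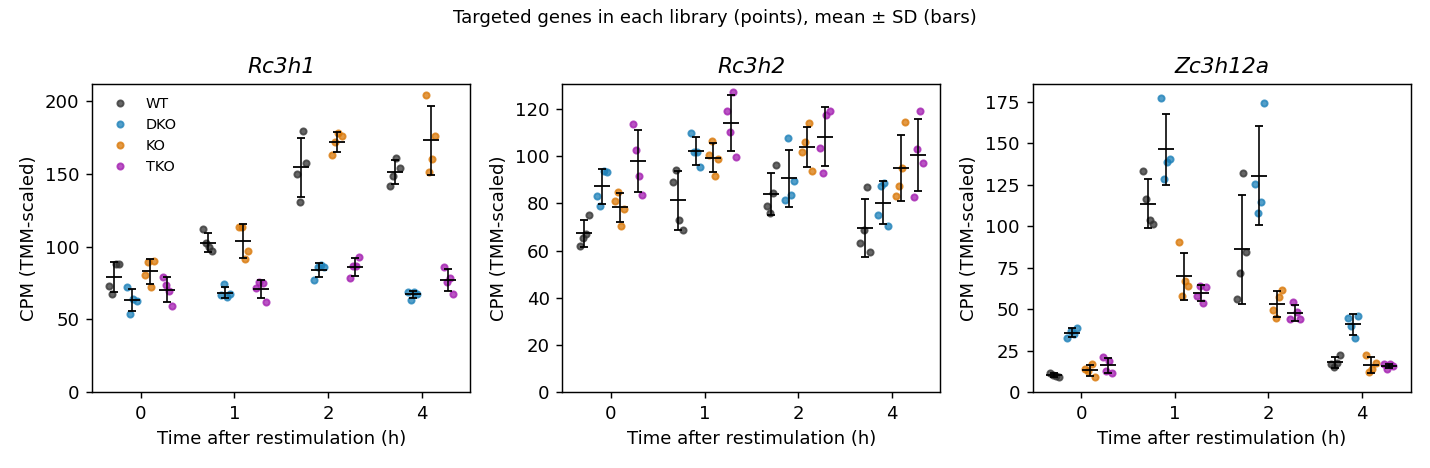
Level of Rc3h1, Rc3h2 and Zc3h12a in CPM (vertical axis) in each genotype at 0, 1, 2 and 4 h after restimulation, with a point for each of the 4 libraries of a group and its mean. Zc3h12a at 1 h lay at or below 90.2 CPM in all 8 KO and TKO libraries and at or above 101.3 CPM in all 8 WT and DKO libraries.

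Restimulation of control cells raised cytokine, chemokine and immediate early genes within 1 h, and by 4 h naive T cell, interferon-stimulated and cell cycle genes were lower. With an estimated correlation these 3 lists had adjusted p = 0.28, 0.37 and 0.7. The transcription factor genes Egr3 (10.44 ± 0.40), Egr2 (9.50 ± 0.33), Nr4a3 (9.67 ± 0.25) and Nr4a1 (8.84 ± 0.28) rose at 1 h. Egr3 went from 1.45 ± 1.83 to 2760 ± 658 normalized counts, and stood at 50 ± 15 at 4 h, with 1 library at 72.4 and the others at 40.7 to 44.4. Il2, the T cell growth factor, rose by 9.07 ± 0.51 at 1 h and 10.42 ± 0.51 at 2 h. Csf2, which encodes GM-CSF, rose by 10.78 ± 0.58 at 2 h. The chemokine genes Ccl3 (10.54 ± 0.46), Ccl4 (10.45 ± 0.46) and Xcl1 (10.60 ± 0.48) and the Th1 cytokine gene Ifng (8.57 ± 0.57) rose at 4 h. Il3 had 2 reads in all at 0 h. Its CPM was 1480 times higher at 1 h (95% interval 410 to 12200), 6050 times at 2 h (1680 to 50000) and 7120 times at 4 h (1970 to 58800), with intervals that cover counting error only. S1pr1, a receptor for exit from lymphoid organs (1 WT library at 704 and the others at 579 to 592 at 0 h), went from 615 ± 59.5 to 7.11 ± 3.06 normalized counts at 4 h (log2 change -6.34 ± 0.41). Arl4c, a small GTPase gene (-5.94 ± 0.27), Ypel3 (-5.22 ± 0.24) and, at 2 h, Nod1 (-4.04 ± 0.35) also fell. The genes with the largest falls at 1 h were Cnr2 (-2.96 ± 0.51), AI467606 (-2.13 ± 0.23) and Gpr146 (-2.15 ± 0.44), the last of which overlaps another gene. Among these genes the highest adjusted p was 0.0001.

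By list, 21 of 21 immediate early genes rose at 1 h (21 adjusted over the list alone). At 2 h 20 rose and 1 fell (20 and 1 adjusted over the list alone), with adjusted p = 0.0017 and 0.093 by camera with an estimated correlation. Of 29 cytokine and chemokine genes 23 rose and 1 fell at 1 h (23 and 1 adjusted over the list alone). At 2 h 26 rose and 1 fell (26 and 1 adjusted over the list alone), with adjusted p = 0.0026 and 0.011 with an estimated correlation. NF-kB pathway genes such as the inhibitor gene Nfkbia (4.58 ± 0.15) and the subunit genes Relb (3.81 ± 0.16) and Rel (4.18 ± 0.17) rose at 1 h. Of that list 19 of 20 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 2.4e-31, adjusted p = 0.00067 with an estimated correlation). At 2 h 18 rose and 0 fell (adjusted p = 0.0088 with an estimated correlation). Among the known Roquin or Regnase-1 targets 13 of 23 rose and 1 fell (13 and 1 adjusted over the list alone) at 1 h. The test gave camera adjusted p = 1.9e-08, adjusted p = 0.093 with an estimated correlation. Among naive T cell genes 1 of 12 rose and 9 fell (1 and 10 adjusted over the list alone) at 4 h (camera adjusted p = 0.00079, adjusted p = 0.28 with an estimated correlation). Klf2 (-4.60 ± 0.36) was among those that fell. Among interferon-stimulated genes 0 of 20 rose and 14 fell (0 and 14 adjusted over the list alone) at 4 h (camera adjusted p = 0.00097, adjusted p = 0.37 with an estimated correlation). Irf1 (-2.82 ± 0.25) and Oas3 (-2.97 ± 0.28) were examples. Among cholesterol synthesis genes 0 of 16 rose and 15 fell (0 and 15 adjusted over the list alone) at 4 h, such as Mvk (-1.92 ± 0.20) and Dhcr7 (-2.21 ± 0.23). Among cell cycle genes 0 of 22 rose and 17 fell (0 and 17 adjusted over the list alone), such as Mki67 (-1.53 ± 0.11) and Top2a (-1.74 ± 0.14). These 2 lists had adjusted p = 0.00026 and 0.00035 by camera and 0.67 and 0.7 with an estimated correlation. Among glycolysis genes 2 of 19 rose and 12 fell (2 and 14 adjusted over the list alone) at 4 h (camera adjusted p = 0.024, adjusted p = 0.81 with an estimated correlation). Among ribosomal protein genes 18 of 25 rose and 0 fell (19 and 0 adjusted over the list alone) at 2 h (camera adjusted p = 0.0013, adjusted p = 0.73 with an estimated correlation). Among heat shock genes 8 of 11 rose and 0 fell (8 and 0 adjusted over the list alone) at 1 h (camera adjusted p = 0.0012, adjusted p = 0.21 with an estimated correlation). The B cell gene Ighm fell over the same time (-3.32 ± 0.24 at 4 h), as did the myeloid gene Ctss (-0.77 ± 0.15). Over all genes, 2761 rose and 1284 fell at 1 h under all 5 scalings, 3992 and 3927 at 2 h, and 3511 and 3983 at 4 h. The counts were 3012 and 2013, 4279 and 4120, and 3979 and 4376 with the main scaling. The share of calls that were higher at 1 h was 59.9%, and 75.7% with the deposited scaling.

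Loss of both Roquin genes raised costimulatory and Tfh genes in cells that had not been restimulated. Icos, a costimulatory receptor gene and known Roquin target, went from 711 ± 246 to 4730 ± 1150 normalized counts at 0 h (2.76 ± 0.40, adjusted p = 1.9e-06). Tnfrsf4, which encodes OX40, rose by 2.14 ± 0.30, the inhibitory receptor gene Ctla4 by 2.84 ± 0.42, the atypical IkB gene Nfkbid by 1.73 ± 0.28, and Irf4 by 1.14 ± 0.21 (highest adjusted p 0.00014). The largest rises were of Ebi3, a cytokine subunit gene (4.28 ± 0.39), Tnfrsf8, which encodes CD30 (3.78 ± 0.73), the transcription factor gene Zbtb32 (3.72 ± 0.51) and the cell death gene Bmf (3.34 ± 0.44). The largest falls were of the interferon-induced membrane protein genes Ifitm3 (-2.69 ± 0.30) and Ifitm1 (-2.38 ± 0.37) and of the chemokine receptor gene Ccr2 (-2.13 ± 0.37), with a highest adjusted p of 0.00039. In other lists the NR4A gene Nr4a3 (1.68 ± 0.25), the AP-1 factor gene Batf (1.44 ± 0.16), Ikzf2, which encodes Helios (1.71 ± 0.33), Gbp5 (1.33 ± 0.21) and Zc3h12d, a relative of Zc3h12a (1.62 ± 0.28), rose (highest adjusted p 0.00035).

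Among Tfh genes 7 of 11 rose and 0 fell (7 and 0 adjusted over the list alone) at 0 h (camera adjusted p = 3.4e-08, adjusted p = 0.0049 with an estimated correlation). They included Slamf6 (2.22 ± 0.25), Sh2d1a, which encodes SAP (1.61 ± 0.18), and Tcf7 (1.00 ± 0.22). Tfh genes also stood apart at 1 h (6 of 11 higher, 7 adjusted over the list alone) and 2 h (6 of 11, 8 adjusted over the list alone), with adjusted p = 0.0049 and 0.047 with an estimated correlation. At 4 h 4 of 11 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00024, adjusted p = 0.092 with an estimated correlation). Among costimulatory receptor genes 5 of 12 rose and 0 fell (8 and 0 adjusted over the list alone) at 0 h (camera adjusted p = 1.2e-07, adjusted p = 0.034 with an estimated correlation). Tnfrsf25 rose by 1.29 ± 0.20 and Tnfrsf1b by 0.88 ± 0.15. Among known Roquin or Regnase-1 targets 10 of 23 rose and 0 fell (10 and 0 adjusted over the list alone) at 0 h (camera adjusted p = 4.8e-07, adjusted p = 0.16 with an estimated correlation). Among NF-kB pathway genes 7 of 20 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 2.5e-06, adjusted p = 0.24 with an estimated correlation). Among cell cycle genes 0 of 22 rose and 8 fell (0 and 13 adjusted over the list alone) at 1 h (camera adjusted p = 3.6e-08, adjusted p = 0.47 with an estimated correlation). Mki67 (-0.62 ± 0.11) and Top2a (-0.58 ± 0.14) fell. Cytokine genes that rose at 0 h included Tnfsf14 (2.88 ± 0.26) and Cd40lg, the ligand of CD40 (1.98 ± 0.26). The B cell gene Cd22 was also higher in DKO cells at 0 h (2.93 ± 0.63, from 3.8 ± 3 to 28.4 ± 8.19 normalized counts).

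After restimulation Nos2, which encodes inducible nitric oxide synthase, rose in DKO against WT cells at 1 h (5.68 ± 0.69) and 2 h (5.52 ± 0.69), as did Ebi3 at 1 h (3.98 ± 0.39), 2 h (4.28 ± 0.39) and 4 h (3.04 ± 0.39). Prickle1, a planar polarity gene, rose at 1 h (3.27 ± 0.23) and 4 h (2.75 ± 0.23), Pdzk1ip1 at 2 h (3.09 ± 0.39) and Ikzf2 at 4 h (2.66 ± 0.33). Ifitm3 fell at 1 h (-2.94 ± 0.30), 2 h (-2.65 ± 0.30) and 4 h (-2.06 ± 0.30). Further falls were of Ccl1 (-2.54 ± 0.40) and Ifitm1 (-2.02 ± 0.37) at 1 h, Pydc3 (-2.23 ± 0.44) at 2 h and Treml2 (-1.48 ± 0.24) at 4 h. Of these genes the highest adjusted p was 0.00033. Tnfrsf8 was not called with limma voom at 1 h (3.43 ± 0.73, adjusted p = 0.0012, 3.2e-08 to 0.07 over alternatives) or 2 h (3.28 ± 0.73, adjusted p = 0.0019, 5.3e-08 to 0.14 over alternatives). Csf2 at 2 h (-2.28 ± 0.58, adjusted p = 0.0075, 0.00011 to 0.069 over alternatives) was not called without DKO 2 h library 3 or with only the groups compared. Csf2 at 4 h (-1.90 ± 0.58, adjusted p = 0.043, 0.0015 to 0.19 over alternatives) was not called under 13 of 21 alternatives. They included the deposited scaling and leaving out DKO libraries 1, 2 or 3 or WT libraries 1, 2, 3 or 4. Under all 5 scalings 740 genes rose and 85 fell at 0 h, 719 and 257 at 1 h, 660 and 194 at 2 h, and 363 and 78 at 4 h. With the main scaling the counts were 864 and 371, 961 and 368, 1284 and 245, and 757 and 109. The totals at 0, 1, 2 and 4 h were 392, 719, 439 and 1544 with only the groups compared. They were 3290, 3572, 3510 and 2534 with the library sets as a block. With the deposited scaling they were 4166 at 0 h and 544 at 4 h. The total at 0 h was 626 without DKO library 3 and 794 and 817 without WT libraries 1 and 2 in turn, and that at 1 h 831 without DKO library 2. At 4 h it was 551, 555 and 432 without DKO libraries 1, 2 and 3 in turn and 525, 552 and 549 without WT libraries 1, 2 and 4 in turn. The share of calls that were higher was 70% at 0 h (53.2 to 97.8% over the scalings), 72.3% at 1 h (51.3 to 83.0%), 84.0% at 2 h (59.4 to 90.5%) and 87.4% at 4 h (67.0 to 93.7%).

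Loss of Regnase-1 raised Icos and other Tfh genes before restimulation. At 0 h Icos went from 711 ± 246 to 3410 ± 676 normalized counts (2.29 ± 0.40, adjusted p = 0.00015), and the NF-kB regulator gene Nfkbiz rose by 1.38 ± 0.21. The cytokine gene Il24 rose (3.56 ± 0.53, adjusted p = 7.6e-06, 1.4e-10 to 0.26 over alternatives) but was not called with limma voom. Other large rises were of Zcchc18 (3.53 ± 0.32, overlapping Slc25a53), Kit, the stem cell factor receptor gene (3.03 ± 0.41), and Prickle1 (2.52 ± 0.23). Ifitm3 fell (-1.90 ± 0.30). Mb21d1, which encodes the DNA sensor cGAS, also fell (-1.48 ± 0.23, adjusted p = 1.4e-05, 6.5e-08 to 0.054 over alternatives), but was not called with only the groups compared. Batf (1.28 ± 0.16), Ikzf2 (2.02 ± 0.33), Ikzf4 (1.32 ± 0.27), Tnfrsf1b (1.00 ± 0.15), Slamf6 (1.29 ± 0.25), Cd40lg (1.69 ± 0.26) and Gbp5 (1.17 ± 0.21, named Gbp2b in the annotation) rose (highest adjusted p 0.002). Among Tfh genes 5 of 11 rose and 0 fell (7 and 0 adjusted over the list alone) at 0 h (camera adjusted p = 5.1e-08, adjusted p = 0.0051 with an estimated correlation). With an estimated correlation adjusted p = 0.0073 at 1 h and 0.023 at 2 h. At 4 h 7 of 11 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.41 with an estimated correlation). Among known Roquin or Regnase-1 targets 3 of 23 rose and 0 fell (5 and 0 adjusted over the list alone) at 0 h (camera adjusted p = 0.00017, adjusted p = 0.38 with an estimated correlation).

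After restimulation Prickle1 rose by 5.01 ± 0.23 at 1 h (adjusted p = 5.7e-24), from 61.9 ± 18.8 to 2020 ± 486 normalized counts. It rose by 4.71 ± 0.23 at 2 h and 3.98 ± 0.23 at 4 h. Pdzk1ip1, a small membrane protein gene, rose by 5.56 ± 0.39, 4.43 ± 0.39 and 3.25 ± 0.39 at 1, 2 and 4 h, with 1 WT library at 160 normalized counts and the others at 66.8 to 82.5 at 4 h. Il24 rose by 4.77 ± 0.53 at 2 h and 4.39 ± 0.53 at 4 h. Usp18, which dampens interferon signalling, rose by 3.32 ± 0.42 at 2 h. Ermn, which encodes the cytoskeletal protein ermin, rose by 4.94 ± 0.59 at 4 h, with 1 KO library at 216 normalized counts against 59.7 to 86.0 in the other 3. For Il24 1 WT library held 158 normalized counts at 2 h (35.9 to 48.5 in the others) and 1 held 161 at 4 h (31.3 to 42.4), and for Prickle1 1 held 146 at 4 h (87.7 to 94.9). Id3 (2.19 ± 0.32), Nfkbiz (1.15 ± 0.21), Icos (2.02 ± 0.40), Ctla4 (1.76 ± 0.42), Ikzf2 (3.13 ± 0.33), Tcf7 (1.79 ± 0.22), Tnfrsf25 (2.55 ± 0.20) and Batf (1.58 ± 0.16) rose at 4 h. Fasl, which encodes the death ligand FasL, fell at 2 h (-2.40 ± 0.38) and 4 h (-1.73 ± 0.38). So did Sirpb1b (-2.36 ± 0.47) and Trpc5 (-2.22 ± 0.49) at 4 h, and Mb21d1 (-1.80 ± 0.23) and Ifitm3 (-1.57 ± 0.30) at 1 h. The highest adjusted p of the genes above from 1 h on was 0.0018. Ccl1 at 1 h (-1.46 ± 0.40, adjusted p = 0.038, 0.0029 to 0.19 over alternatives) was not called with no filter, a filter at a mean of 1, a pseudocount of 0.1 or without KO libraries 1, 2 or 4 or WT libraries 2, 3 or 4. Cd83 at 2 h (-2.05 ± 0.58, adjusted p = 0.022, 0.00049 to 0.086 over alternatives) was not called without KO library 1 or WT library 4. The CD8 T cell gene Cd8b1 (1.60 ± 0.40), Ighm (1.34 ± 0.24) and Ctss (1.29 ± 0.15) were higher at 4 h as well. Under all 5 scalings 156 genes rose and 12 fell at 0 h, 209 and 37 at 1 h, 356 and 172 at 2 h, and 576 and 1774 at 4 h. With the main scaling the counts were 186 and 27, 297 and 53, 756 and 203, and 3508 and 1877. The totals at 0, 1 and 2 h were 94, 219 and 365 with only the groups compared, and 972, 1465, 2858 and 8549 at the 4 times with the library sets as a block. With the deposited scaling they were 2470 at 0 h and 2881 at 4 h. The total at 1 h was 231 and 215 without KO libraries 2 and 4 in turn and 218 and 225 without WT libraries 3 and 4 in turn. At 2 h it was 588 and 1598 without WT libraries 1 and 3 in turn, and at 4 h 3582 without KO library 1. The share of calls that were higher was 87.3% at 0 h (74.6 to 99.1% over the scalings), 84.9% at 1 h (60.3 to 90.0%), 78.8% at 2 h (51.3 to 86.3%). At 4 h it was 65.1%, and turned to 20% with the deposited scaling and 36.1% with median-of-ratios scaling. Olfactory and vomeronasal receptor genes, which belong to other tissues, together held 123.7 ± 20.1 CPM in WT and 53.3 ± 10.4 in KO cells at 4 h (exact permutation p = 0.0286). Keratin genes held 6.0 ± 0.1 and 4.7 ± 1.5 (exact p = 0.1429). Genes below 5 CPM made up 60.1% of the falls at 4 h.

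**Figure D2:**
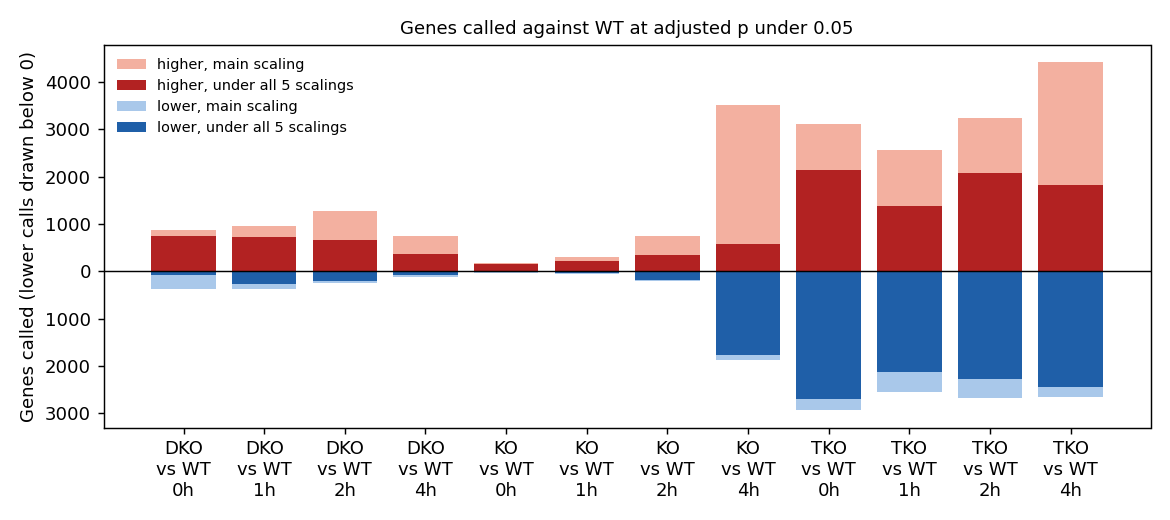
Number of genes called higher (up) and lower (down) by limma at an adjusted p under 0.05 in the contrasts shown, counts in genes. The counts for the triple knockout against control cells at 4 h were 4423 higher and 2658 lower, and those for the Roquin knockout at 4 h were 757 and 109.

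Loss of all 3 genes raised some transcripts from near the limit of detection. At 0 h Sema3b, a semaphorin gene, had 2 reads in all 4 WT libraries together and 1694 in TKO cells, a ratio of CPM of 856 (95% interval 237 to 7080, counting error only). Pdzk1ip1 had 3 and 1868 reads, a ratio of 629 (215 to 3050). Ermn went from 3.27 ± 3.14 to 729 ± 199 normalized counts (7.64 ± 0.59, adjusted p = 5.2e-15). Kit rose by 5.39 ± 0.41, Tnfrsf8 by 5.63 ± 0.73, Il24 by 5.06 ± 0.53, Fam43a by 4.80 ± 0.33 and Bmf by 4.72 ± 0.44. The largest falls were of Pydc3 (-3.11 ± 0.44) and Pydc4 (-2.84 ± 0.38), pyrin domain genes, Samd3 (-2.92 ± 0.58), Nyap2 (-2.87 ± 0.46), Dpy19l2 (-2.81 ± 0.49) and Rtn4rl1 (-2.81 ± 0.34). The highest adjusted p of these genes was 9.6e-05. Those that fell, except Pydc3, had 200 to 384 reads in WT cells. A shared fall with olfactory receptor genes was not tested. Icos reached 10100 ± 2400 normalized counts (3.84 ± 0.40). Of the other known targets Ctla4 (2.97 ± 0.42), Tnfrsf4 (2.36 ± 0.30), Nfkbid (2.00 ± 0.28), Nfkbiz (1.91 ± 0.21), Rel (1.40 ± 0.17), Irf4 (1.30 ± 0.21), Il2ra (0.78 ± 0.16) and Tfrc (0.68 ± 0.14) rose. Gata3 fell (-0.95 ± 0.23), with a highest adjusted p of 0.0011.

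Among known Roquin or Regnase-1 targets 12 of 23 rose and 1 fell (14 and 1 adjusted over the list alone) in TKO cells at 0 h (camera adjusted p = 0.00016, adjusted p = 0.38 with an estimated correlation). Among NF-kB pathway genes 13 of 20 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 6.1e-05, adjusted p = 0.39 with an estimated correlation). Nfkbia rose by 2.86 ± 0.15 and Tnip1 by 1.27 ± 0.14. Among Tfh genes 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 4.3e-06, adjusted p = 0.021 with an estimated correlation), such as Slamf6 (2.78 ± 0.25) and Tcf7 (1.79 ± 0.22). At 1 h 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 2.2e-06, adjusted p = 0.016 with an estimated correlation). Treg genes that rose included Ikzf2 (2.96 ± 0.33), Ikzf4 (1.97 ± 0.27) and Il10 (3.95 ± 0.59). Of that list 6 of 11 rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.042, adjusted p = 0.5 with an estimated correlation). Among costimulatory receptor genes 8 of 12 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00089, adjusted p = 0.26 with an estimated correlation). Among cytotoxic effector genes 3 of 12 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.28, adjusted p = 0.76 with an estimated correlation). Nkg7 (-2.07 ± 0.32), Fasl (-2.35 ± 0.38) and Eomes (-2.21 ± 0.46) were lower and Gzmf (2.22 ± 0.51) higher. Batf (2.60 ± 0.16), the hexokinase gene Hk2 (2.03 ± 0.27) and Zc3h12d (2.18 ± 0.28) rose. The cell cycle genes Mki67 (-0.74 ± 0.11), Top2a (-0.70 ± 0.14) and Ccna2 (-0.88 ± 0.19) fell. Of that list 0 of 22 rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 0.00015, adjusted p = 0.67 with an estimated correlation). In the Th1 list 1 of 13 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.75). The B cell genes Ighm (1.62 ± 0.24), Cd79b (2.32 ± 0.45) and Cd22 (3.10 ± 0.63) were higher and Fcer2a (-2.05 ± 0.60) lower. The myeloid gene Ctss (0.83 ± 0.15) was higher.

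At 4 h after restimulation Ermn stood at 1030 ± 331 normalized counts in TKO cells (8.28 ± 0.59). Sema3b (6.42 ± 0.65), Tnfrsf8 (4.99 ± 0.73), Ebi3 (4.73 ± 0.39), the cytokine gene Il9 (4.71 ± 0.65), the syndecan gene Sdc4 (4.32 ± 0.54), Ikzf2 (4.24 ± 0.33) and Kit (4.19 ± 0.41) rose. Fasl was 36.3 ± 17.4 normalized counts in TKO and 335 ± 101 in WT cells (-3.23 ± 0.38). Wnt3 (-3.45 ± 0.52), Ccl1 (-3.27 ± 0.40), Chl1 (-3.06 ± 0.75), Samd3 (-2.97 ± 0.58) and Csf2 (-2.94 ± 0.58) fell too. Of these genes the highest adjusted p was 0.00097. Known targets that rose included Id3 (3.38 ± 0.32), Ctla4 (3.27 ± 0.42), Icos (2.50 ± 0.40, with 1 TKO library at 1710 normalized counts against 4260 to 4560 in the other 3), Nfkbiz (1.75 ± 0.21), Nfkbid (1.18 ± 0.28), Gata3 (1.11 ± 0.23) and Il1r1 (2.16 ± 0.66). Tnf fell (-1.27 ± 0.34), with a highest adjusted p of 0.0065. In other lists Tnfrsf25 (3.20 ± 0.20), Tcf7 (2.67 ± 0.22), Batf (2.00 ± 0.16) and Il21 (3.27 ± 0.60) rose. Nkg7 (-2.09 ± 0.32), Klf3 (-2.10 ± 0.26) and Lrrc32 (-1.49 ± 0.33) fell (highest adjusted p 0.00027). Cholesterol synthesis genes were higher than the shift of all genes, with Fdft1 0.99, Dhcr7 1.09 and Mvd 1.22 above the median log2 change (Fdft1 and Mvd each overlap another gene). Of the list 12 of 16 rose and 0 fell (14 and 0 adjusted over the list alone), or 6 to 15 members higher depending on the scaling (camera adjusted p = 0.0041, adjusted p = 0.75 with an estimated correlation). Among cytotoxic effector genes 0 of 12 rose and 4 fell (0 and 4 adjusted over the list alone) at 4 h (camera adjusted p = 0.028, adjusted p = 0.47 with an estimated correlation). Ighm (2.39 ± 0.24), Cd79b (2.24 ± 0.45), Ctss (1.60 ± 0.15) and Cd8b1 (1.62 ± 0.40) were higher and Pax5 (-1.59 ± 0.48) and Cr2 (-2.37 ± 0.54) lower in the same libraries.

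At 1 h the largest rises in TKO cells were of Pdzk1ip1 (7.87 ± 0.39), Sema3b (7.59 ± 0.65), Ermn (7.58 ± 0.59) and Fam43a (6.27 ± 0.33). At 2 h they were of Ermn (7.84 ± 0.59), Sema3b (6.97 ± 0.65), Tnfrsf8 (5.84 ± 0.73) and Pdzk1ip1 (5.47 ± 0.39). The largest falls were of Pydc3 (-3.89 ± 0.44), Ccl1 (-2.95 ± 0.40) and Ly6c1 (-2.90 ± 0.47) at 1 h. At 2 h they were of Fasl (-4.27 ± 0.38), Ccl1 (-3.27 ± 0.40) and Chst15 (-3.14 ± 0.40, overlapping Fgfr2 on the same strand). The highest adjusted p of these genes was 3.3e-06. Under all 5 scalings 2136 genes rose and 2707 fell at 0 h, 1391 and 2123 at 1 h, 2073 and 2270 at 2 h, and 1818 and 2452 at 4 h. With the main scaling the counts were 3114 and 2932, 2557 and 2548, 3242 and 2672, and 4423 and 2658. At 4 h 10 genes were called in opposite directions under different scalings. The share of calls that were higher was 51.5% at 0 h (37.6 to 58.9% over the scalings), 50.1% at 1 h (22.7 to 59.4%), 54.8% at 2 h (33.2 to 65.3%) and 62.5% at 4 h (33.9 to 72.3%). The total at 0 h was 3715 with only the groups compared. Genes below 5 CPM made up 50.2% of the falls at 0 h and 60.9% at 4 h. Olfactory and vomeronasal receptor genes together held 165.8 ± 44.2 CPM in WT and 69.6 ± 8.9 in TKO cells at 0 h, and 123.7 ± 20.1 and 40.2 ± 4.5 at 4 h (exact permutation p = 0.0286 for each). Keratin genes held 8.2 ± 2.4 and 6.1 ± 1.9 at 0 h, and 6.0 ± 0.1 and 5.1 ± 1.1 at 4 h (exact p = 0.2286 for each).

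**Figure D3:**
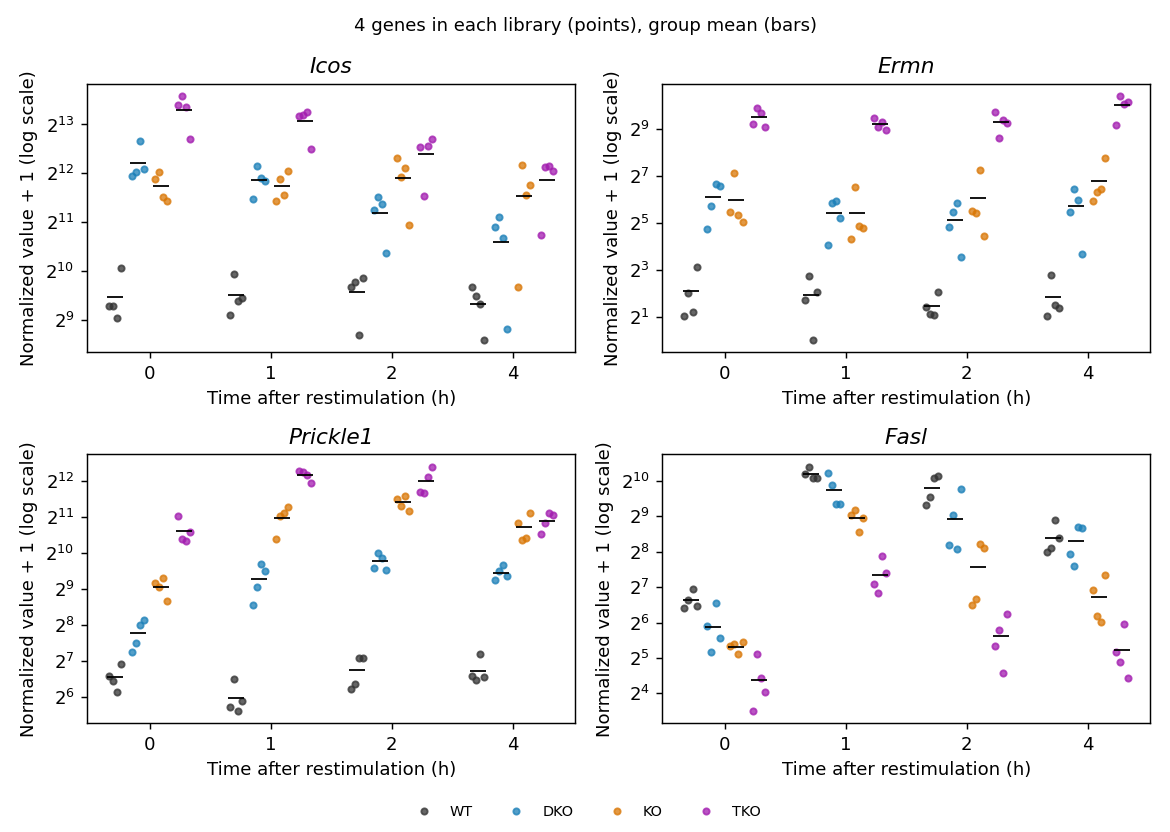
Normalized counts of Icos, Ermn, Prickle1 and Fasl (vertical axes) in each genotype at each time, with a point for each of the 4 libraries of a group and a bar at the group mean. At 0 h Icos averaged 711 in WT, 4730 in DKO, 3410 in KO and 10100 in TKO cells, and Fasl at 1 h averaged 1170, 859, 492 and 162 in the same order.

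The key genes lie in GRCm38 as follows. Icos is ENSMUSG00000026009, chromosome 1, 60977927 to 61000320, plus strand. Ermn is ENSMUSG00000026830, chromosome 2, 58045113 to 58052864, minus strand. Pdzk1ip1 is ENSMUSG00000028716, chromosome 4, 115088708 to 115093899, plus strand. Sema3b is ENSMUSG00000057969, chromosome 9, 107597674 to 107609229, minus strand. Prickle1 is ENSMUSG00000036158, chromosome 15, 93499114 to 93595891, minus strand. Fasl is ENSMUSG00000000817, chromosome 1, 161780689 to 161788495, minus strand.

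Against DKO cells at 0 h, TKO cells had more Ermn (3.55 ± 0.59), Pdzk1ip1 (3.55 ± 0.39), Sema3b (3.55 ± 0.65), Il24 (3.17 ± 0.53), Nfkbia (1.90 ± 0.15) and Batf (1.17 ± 0.16). They had less Lypd6b (-2.20 ± 0.33), Samd3 (-2.29 ± 0.58) and Entpd1, which encodes CD39 (-1.51 ± 0.23). Il1rapl1 (-1.91 ± 0.49, adjusted p = 0.0061, 5.9e-05 to 0.083 over alternatives) was not called without TKO library 4, with only the groups compared, or without the libraries with the highest share of reads in the 10 top loci. At 4 h they had more Ermn (4.56 ± 0.59), Ociad2 (3.68 ± 0.44), Prkar1b, a protein kinase A subunit gene (3.35 ± 0.25), Kit (3.30 ± 0.41), Nfkbiz (1.67 ± 0.21), Id3 (2.39 ± 0.32) and Tnfrsf25 (2.17 ± 0.20). They had less Fasl (-3.10 ± 0.38), Mpzl2 (-2.77 ± 0.60) and Amica1 (-2.47 ± 0.18). Ighm was higher in TKO than in DKO cells at both times (1.05 ± 0.24 and 1.54 ± 0.24). The highest adjusted p of the called genes was 0.0061. Against KO cells at 0 h, TKO cells had more Tnfrsf8 (4.74 ± 0.73), Il9r (3.92 ± 0.52), Tox2 (3.84 ± 0.51), Ermn (3.74 ± 0.59), Nfkbid (2.27 ± 0.28), Nfkbia (1.98 ± 0.15), Tnfrsf4 (1.99 ± 0.30), Rel (1.01 ± 0.17) and Icos (1.55 ± 0.40). They had less Pydc3 (-2.41 ± 0.44) and Obox1 (-2.06 ± 0.47, overlapping Obox3), with a highest adjusted p of 0.0048. At 4 h they had more Trp73 (3.79 ± 0.49), Ermn (3.34 ± 0.59), Ebi3 (3.22 ± 0.39) and Wnt10b (3.21 ± 0.56) and less Amica1 (-1.67 ± 0.18), Gbp2 (-1.12 ± 0.19) and Klf3 (-1.28 ± 0.26), with a highest adjusted p of 0.0012.

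Among known Roquin or Regnase-1 targets 8 of 23 rose and 0 fell (10 and 0 adjusted over the list alone) in TKO against KO cells at 0 h (camera adjusted p = 0.0057, adjusted p = 0.57 with an estimated correlation). Among ribosomal protein genes 6 of 25 rose and 0 fell (7 and 0 adjusted over the list alone) in TKO against DKO cells (camera adjusted p = 7.5e-05, adjusted p = 0.66 with an estimated correlation, with 0 members called under the deposited scaling). Under all 5 scalings TKO against DKO cells had 369 genes higher and 942 lower at 0 h and 481 and 740 at 4 h, out of 1407 and 978 and of 1208 and 796. TKO against KO cells had 686 higher and 1429 lower at 0 h and 279 and 79 at 4 h, out of 1846 and 1440 and of 317 and 104. Genes below 5 CPM were 49.1 and 41.1% of the falls against DKO and 50.1 and 6.7% against KO cells at 0 and 4 h. The total against DKO cells at 0 h was 874 with only the groups compared. It was 1319 without DKO library 4 and 1526 and 1216 without TKO libraries 1 and 4 in turn. At 4 h it was 719 without DKO library 4 and 1311 and 1167 without TKO libraries 1 and 2 in turn. Against KO cells it was 2064 without KO library 1 at 0 h, and 258 and 232 without TKO libraries 2 and 4 in turn at 4 h. The share of higher calls was 59.0% (15.9 to 59.0% over the scalings) and 60.3% (31.1 to 69.6%) against DKO cells at 0 and 4 h. Against KO cells it was 56.2% (22.9 to 56.2%) and 75.3% (64.7 to 80.3%).

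For 118 genes at 0 h and 27 at 4 h the triple knockout departed from the sum of the Roquin and Regnase-1 log2 changes. Zc3h12a itself lay below the sum at 0 h (-1.52 ± 0.27, adjusted p = 0.00099). At 0 h Otud3 (2.21 ± 0.30) and Prkar1b (2.20 ± 0.36) exceeded the sum. Ncf1, an NADPH oxidase subunit gene that overlaps Gtf2ird2, fell short of it (-1.80 ± 0.27), with a highest adjusted p of 0.00099. At 4 h Prkar1b (2.07 ± 0.36) and Fam227b (2.90 ± 0.50, overlapping Galk2) exceeded the sum, and Prickle1 (-2.54 ± 0.32) and Amica1 (-1.49 ± 0.26) lay below it, with a highest adjusted p of 0.0011. Prickle1 at 4 h averaged 105 ± 27.1, 700 ± 84.9, 1680 ± 429 and 1910 ± 342 normalized counts in WT, DKO, KO and TKO cells. Sums of counts were not tested. At 0 h 99 genes lay above and 19 below the sum (19 and 17 under all 5 scalings). At 4 h 14 and 13 did (12 and 5). The share above was 83.9% at 0 h (1.4 to 87.6% over the scalings) and 51.9% at 4 h (40.0 to 78.3%). With only the groups compared the counts were 20 and 43, and with the library sets as a block 1254 and 363. The total at 0 h was 1803 with the deposited scaling (25 above and 1778 below), 185 with median-of-ratios scaling, 74 with TMM over genes of at least 5 CPM and 57 with TMM over all genes. Left out in turn, DKO libraries 1 and 2 gave counts of 60 and 239 at 0 h. KO 1 and 2 gave 74 and 58, and TKO 2 and 4 gave 388 and 45. WT 1, 2, 3 and 4 gave 57, 63, 59 and 575. At 4 h the count was 17 without DKO library 1 and 42 and 16 without WT libraries 3 and 4 in turn. At 0 h the Th1 list had a median of -0.58 with no member called (camera adjusted p = 0.0026, adjusted p = 0.46 with an estimated correlation).

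The effects of the Roquin and the Regnase-1 knockout were compared with each other over all tested genes. At 0 h 152 genes rose in both (10 would be shared by independent lists of those lengths), 19 fell in both (0.6) and 0 moved in opposite directions. At 4 h 617 rose in both (164.5), 46 fell in both (12.7) and 5 moved in opposite directions. With the controls divided between the 2 comparisons in 6 ways, 55 to 79 rose and 4 to 7 fell in both at 0 h, and 149 to 238 and 6 to 9 at 4 h. The deposited scaling gave 1955 and 12 at 0 h (2 opposite) and 195 and 95 at 4 h, and median-of-ratios scaling 128 and 44, and 270 and 76. Across genes, which are not independent replicates, Pearson's r was 0.708 at 0 h and 0.786 at 4 h, where groups simulated without change against the same control libraries gave 0.502 and 0.495. The covariance was 0.145 at 0 h and 0.283 at 4 h, against 0.058 and 0.057 from the shared controls alone. With the divided controls r was 0.068 to 0.402 and the covariance 0.022 to 0.102 at 0 h. At 4 h they were 0.577 to 0.653 and 0.235 to 0.262. With the library sets as a block, r with divided controls was 0.213 to 0.442 at 0 h and 0.598 to 0.645 at 4 h. The simulation takes libraries as independent.

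The change from 0 to 4 h was also compared between each knockout and control cells. In TKO cells P2ry1, a purine receptor gene (3.99 ± 0.54), Calcrl (2.83 ± 0.52), Id3 (2.51 ± 0.46), Gata3 (2.06 ± 0.33) and Fam227b (2.90 ± 0.50, overlapping Galk2) changed more positively than in WT cells. Pdzk1ip1 (-4.48 ± 0.56), Adora2b (-4.45 ± 0.63), Epha2 (-4.24 ± 0.60), Tnfsf14 (-4.05 ± 0.37), Nfkbia (-1.82 ± 0.22), Nr4a3 (-1.94 ± 0.35) and Irf4 (-1.22 ± 0.30) changed less positively, with a highest adjusted p of 0.0052. Of cytokine and chemokine genes 2 had a higher and 9 a lower change (3 and 16 adjusted over the list alone, camera adjusted p = 3.4e-08, adjusted p = 0.13 with an estimated correlation). Of NF-kB pathway genes 0 had a higher and 5 a lower change (1 and 7 adjusted over the list alone, camera adjusted p = 7.5e-09, adjusted p = 0.12 with an estimated correlation). In KO cells Hrh2, a histamine receptor gene (2.08 ± 0.28), and Id3 (2.20 ± 0.46) had a higher and Pou2f2 (-2.44 ± 0.28) and Clnk (-2.80 ± 0.55) a lower change, with a highest adjusted p of 0.0038. In DKO cells Gpr155 (1.67 ± 0.27) and Prickle1 (1.55 ± 0.32) had a higher change (highest adjusted p 0.0078). Tnfsf14 (-2.53 ± 0.37, adjusted p = 3.4e-05, 9.4e-09 to 0.074 over alternatives) and Pdzk1ip1 (-2.61 ± 0.56, adjusted p = 0.0092, 0.00029 to 0.43 over alternatives), which were not called with limma voom, had a lower one. Of cholesterol synthesis genes 3 had a higher change in DKO cells (12 adjusted over the list alone, camera adjusted p = 4.9e-10, adjusted p = 0.36 with an estimated correlation). In all, 772 and 299 genes changed more and less positively in TKO cells (253 and 241 under all 5 scalings), 315 and 39 in KO cells (15 and 24) and 79 and 54 in DKO cells (7 and 42). The share with a higher change was 72.1% in TKO (17.5 to 83.0% over the scalings), 89.0% in KO (1.9 to 93.0%) and 59.4% in DKO cells (0.9 to 64.7%). With the library sets as a block the totals were 2632, 3201 and 1222. The count for DKO cells was 846 with the deposited scaling and 75 with only the groups compared. Left out in turn, DKO 0 h library 3 gave 58 and DKO 4 h 1, 2 and 3 gave 82, 80 and 73. WT 0 h 1, 3 and 4 gave 73, 71 and 351, and WT 4 h 1, 2 and 4 gave 62, 77 and 81. The count for KO cells was 945 with the deposited scaling, 672 with TMM over all genes and 110 with median-of-ratios scaling. It was 66 with TMM over genes of at least 5 CPM, 207 with no filter and 133 with only the groups compared. Left out in turn, KO 0 h libraries 1 and 3 gave 163 and 209, and KO 4 h 2 and 4 gave 232 and 154. WT 0 h 1, 3 and 4 gave 235, 100 and 1077, and WT 4 h 1, 2 and 4 gave 199, 228 and 197.

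The authors' deposited table had 0 calls opposite in direction to those made here in its 19 comparisons, and of its calls in genes tested here 52.9% (DKO at 4 h) to 99.6% (WT at 2 h) were shared.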

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

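The ranges of adjusted p include the tests named with the sensitivity tests as chosen after the data were seen, and the splits within sets were chosen after the result was seen as well. Over 16 groups of 4 libraries, in 4 of 64 comparisons within a group for reads, mitochondrial share and other library measures, and in 22 of 176 for genes, 1 library lay far from the other 3. Chance alone marks about 1 in 20, or 3.2 and 8.8 here. Read totals stood apart in 1 KO 0 h library (8348181 reads against 7103687 to 7280721 in the other 3), 1 TKO 1 h library (8895490 against 6705006 to 7072521) and 1 WT 1 h library (11314436 against 6956277 to 7620170). The share of reads in mitochondrial genes was 0.503% in 1 TKO 2 h library (0.609 to 0.621% in the others), and Rc3h1 was 76.8 CPM in 1 DKO 2 h library (85.6 to 87.2).

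The cytokine gene Il24 stood apart in 5 groups, in normalized counts. It was 1090 in 1 DKO 2 h library against 131 to 170 in the other 3, 774 in 1 DKO 4 h library against 117 to 145, 1870 in 1 TKO 4 h library against 796 to 832, 158 in 1 WT 2 h library against 35.9 to 48.5, and 161 in 1 WT 4 h library against 31.3 to 42.4. Icos was low in 1 TKO 1 h library (5810 against 9300 to 9740) and in 1 TKO 4 h library (1710 against 4260 to 4560). Ermn was high in 1 library each of KO 0 h (137 against 31.8 to 43.2), KO 1 h (91.7 against 19.1 to 28.2), KO 4 h (216 against 59.7 to 86.0) and WT 4 h (5.78 against 1.04 to 1.83). Pdzk1ip1 was low in 1 library of DKO 0 h (22.1 against 43.4 to 47.8) and DKO 1 h (25.7 against 52.0 to 56.6), listed at 0 in 1 WT 0 h library (0.866 to 1.02 in the others) and high in 1 WT 4 h library (160 against 66.8 to 82.5). Prickle1 was 146 in 1 WT 4 h library (87.7 to 94.9 in the others). Egr3 was 3870 in 1 KO 1 h library (2100 to 2270) and 72.4 in 1 WT 4 h library (40.7 to 44.4). S1pr1 was 504 in 1 KO 0 h library (569 to 580), 267 in 1 TKO 0 h library (466 to 487) and 704 in 1 WT 0 h library (579 to 592).

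Libraries of different genotypes also moved together within a time. The libraries of a time were arranged in 4 sets of 1 library per genotype, so that deviations from the group means correlated best within sets over 6341 genes. The same WT partner was found from 2 disjoint parts of the genes for 48 of 48 knockout libraries, which is consistent with a batch, culture or animal shared by the libraries of a set, although any factor that acts on a whole library would also give it. With the background of reads in genes of other tissues removed, 48 of 48 kept their partner, which argues against that background as the cause. With the share of reads in the 10 most abundant loci removed, 31 of 48 kept it, which leaves that share open, and the design names no biological group for the sets, so no biological explanation was tested.

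By limma 118 genes departed from additivity of log2 changes at 0 h. Values above the sum need not be rises, as Ifitm3 and Ifitm1 fell in DKO cells. The triple knockout exceeded the sum of the other effects for Ifitm3 (2.37 ± 0.43, adjusted p = 0.0014, 7.6e-06 to 0.067 over alternatives), Otud3 (2.21 ± 0.30), Prkar1b (2.20 ± 0.36) and Ifitm1 (2.19 ± 0.52, adjusted p = 0.021, 0.0026 to 0.34 over alternatives). It lay below the sum for Zcchc18 (-2.20 ± 0.45, adjusted p = 0.0068, 0.00017 to 0.23 over alternatives, overlapping Slc25a53), Ms4a4c (-1.83 ± 0.44, adjusted p = 0.027, 0.00021 to 0.12 over alternatives) and Ncf1 (-1.80 ± 0.27, overlapping Gtf2ird2). At 4 h 27 genes departed, with Synpo2 (2.91 ± 0.64, adjusted p = 0.029, 0.00034 to 0.13 over alternatives), Fam227b (2.90 ± 0.50, overlapping Galk2), Bicd1 (2.07 ± 0.47, adjusted p = 0.035, 0.0026 to 0.24 over alternatives) and Prkar1b (2.07 ± 0.36) above the sum and Prickle1 (-2.54 ± 0.32), Kcnk6 (-1.71 ± 0.40, adjusted p = 0.047, 0.00064 to 0.15 over alternatives) and Amica1 (-1.49 ± 0.26) below it. Where a range of adjusted p is given, the call was lost under at least 1 alternative. Left out in turn, DKO libraries 1 and 3, KO 2, TKO 3 and WT 2 and 3 ended the call of Ifitm1. DKO 1 and 4, KO 1 and 4, TKO 3 and WT 1 and 2 ended that of Ms4a4c. At 4 h DKO 1 and 3, KO 2 and 4, TKO 1 and WT 1 and 4 ended that of Synpo2. DKO 1, 2 and 4, KO 1, 3 and 4, TKO 1, 2 and 4 and WT 2, 3 and 4 ended that of Bicd1. DKO 1, 2, 3 and 4, KO 1, 2 and 3, TKO 3 and 4 and WT 1, 2 and 4 ended that of Kcnk6. The sets above, found in the same data, were a block, and residuals of the additive fit were exchanged within sets. Only the real 1 of 100 splits gave as many genes at 0 h and at 4 h. Sets so found cannot exclude chance. The real counts, with only these groups fitted, were 182 and 656, and the highest others 168 and 109. Splits without the sets (2 and 4 of 100 as large, real counts 20 and 43, highest others 2272 and 2348) mixed genotypes that differ in more genes, so they say nothing about chance.

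The change from 0 to 4 h differed from that of WT cells for 133 genes in DKO, 354 in KO and 1071 in TKO cells. In DKO cells it was higher for Gpr155 (1.67 ± 0.27), Prickle1 (1.55 ± 0.32), Ccnj (1.49 ± 0.39, adjusted p = 0.047, 0.0047 to 0.36 over alternatives), Ppargc1b (1.43 ± 0.34, adjusted p = 0.022, 0.0011 to 0.097 over alternatives) and Gata3 (1.29 ± 0.33, adjusted p = 0.039, 0.00018 to 0.12 over alternatives), and lower for Zbtb32 (-3.19 ± 0.72, adjusted p = 0.019, 2.1e-05 to 0.31 over alternatives), Pdzk1ip1 (-2.61 ± 0.56, adjusted p = 0.0092, 0.00029 to 0.43 over alternatives), Tnfsf14 (-2.53 ± 0.37, adjusted p = 3.4e-05, 9.4e-09 to 0.074 over alternatives) and Irf4 (-1.14 ± 0.30, adjusted p = 0.041, 0.0002 to 0.15 over alternatives). Zbtb32 was not called without DKO 0 h library 3, nor Ppargc1b without DKO 0 h library 4, WT 0 h library 3 or WT 4 h library 2. Left out in turn, DKO 0 h libraries 1, 2 and 3, DKO 4 h 1, 2, 3 and 4, WT 0 h 3 and 4 and WT 4 h 1, 2 and 4 ended the call of Ccnj. DKO 0 h 2 and 4, DKO 4 h 1, 2 and 3, WT 0 h 3 and 4 and WT 4 h 1, 2 and 4 ended that of Gata3. DKO 0 h 3 and 4, DKO 4 h 3 and 4, WT 0 h 1, 2 and 3 and WT 4 h 1, 2 and 4 ended that of Irf4. In KO cells it was higher for P2ry1 (2.38 ± 0.54, adjusted p = 0.0099, 0.00076 to 0.053 over alternatives), Id3 (2.20 ± 0.46), Calcrl (2.19 ± 0.52, adjusted p = 0.015, 2.5e-07 to 0.12 over alternatives), Hrh2 (2.08 ± 0.28) and Gata3 (1.39 ± 0.33, adjusted p = 0.014, 4.4e-05 to 0.12 over alternatives), and lower for Cd83 (-2.99 ± 0.82, adjusted p = 0.039, 0.00072 to 0.36 over alternatives), Clnk (-2.80 ± 0.55) and Pou2f2 (-2.44 ± 0.28). Calcrl was not called without KO 4 h library 4 or WT 0 h library 3, nor Cd83 without 1 of KO 0 h libraries 1 and 3, KO 4 h 2 and 4, WT 0 h 1, 2 and 3 and WT 4 h 1, 3 and 4. In TKO cells it was higher for P2ry1 (3.99 ± 0.54), Fam227b (2.90 ± 0.50, overlapping Galk2), Calcrl (2.83 ± 0.52), Id3 (2.51 ± 0.46) and Gata3 (2.06 ± 0.33). It was lower for Pdzk1ip1 (-4.48 ± 0.56), Adora2b (-4.45 ± 0.63), Epha2 (-4.24 ± 0.60), Tnfrsf4 (-1.76 ± 0.42, adjusted p = 0.0049, 2.2e-06 to 0.057 over alternatives), Irf4 (-1.22 ± 0.30), Rel (-0.88 ± 0.25, adjusted p = 0.018, 9.5e-05 to 0.07 over alternatives) and Csf2 (-3.16 ± 0.83, adjusted p = 0.011, 0.00014 to 0.6 over alternatives), and Rel was not called without WT 0 h libraries 1 or 2 or WT 4 h library 3. With the sets as a block and exchange within sets, 2 of 100 splits, the real one included, gave as many genes for DKO, 1 for KO and 1 for TKO cells. As the sets were found in the same data, this cannot exclude chance, and for DKO cells 1 other split gave more genes. The real counts were 644, 4075 and 2117, and the highest others 731, 3295 and 405. Splits without the sets (3, 4 and 5 of 100 as large, real counts 75, 133 and 878, highest others 642, 6074 and 4203) mixed genotypes within a time, so they too say nothing about chance.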

How the results depend on the processing

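Chosen after the data were seen were the deposited scaling, TMM over all genes and over genes of at least 5 CPM, and limma voom. So were leaving out the library of each group with the highest share of reads in the 10 top loci, and the library sets as a block. No paired analysis was possible by replicate number, because the deposited lists carry none. A fit with the library sets found in the data was run between genotypes, while the sets lie within a time and cannot serve the contrasts of times, and DESeq2 was not run because the deposited values are not counts. Of 1313 values for named genes none that was called changed sign under an alternative that tested it. Without 1 library, 10230 of 11496 such values kept their side of the threshold and sign, 1232 lost the call, 8 gained one, 26 not called in either changed sign, and 308 of the 1313 lost it without at least 1 library. Calls lost by the other settings were 186 on only the groups compared, 147 with the deposited scaling, 126 with TMM over genes of at least 5 CPM, 123 without the libraries of highest top-10 share, 110 with limma voom, 90 with median-of-ratios scaling, 62 with no filter, 49 with a filter at a mean of 1, 37 and 20 with pseudocounts of 0.1 and 5, 28 with TMM over all genes and 0 of 1248 with a filter at 5 CPM, which left 65 untested, and 0 of 1032 with the library sets, which left 281 untested. Calls gained were 10 with the deposited scaling, 10 with the library sets, 4 with TMM over all genes and 0 to 3 with each other setting. Values not called in either changed sign for 9 with the deposited scaling, 6 with TMM over genes of at least 5 CPM, 4 with TMM over all genes, 2 with median-of-ratios scaling, 1 with limma voom and 1 without the libraries of highest top-10 share. Genes of few reads were limited by depth.

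Some counts of called genes moved by more than 1.5 times, and the cause was not tested. With only the groups compared DKO against WT went from 1235 to 392 at 0 h, 1329 to 719 at 1 h, 1529 to 439 at 2 h and 866 to 1544 at 4 h. KO against WT went from 213 to 94 at 0 h, 350 to 219 at 1 h and 959 to 365 at 2 h. TKO went from 6046 to 3715 against WT and from 2385 to 874 against DKO cells at 0 h. Non-additivity went from 118 to 20 at 0 h and from 27 to 43 at 4 h, and the difference in response from 133 to 75 in DKO and 354 to 133 in KO cells. With the deposited scaling the counts were 4166 for DKO and 2470 for KO cells at 0 h, 544 and 2881 at 4 h, 1803 for non-additivity at 0 h, and 846 and 945 for the difference in response in DKO and KO cells. With median-of-ratios scaling they were 576 for DKO and 3096 for KO cells at 4 h, 185 for non-additivity at 0 h and 110 for the KO response. With TMM over genes of at least 5 CPM they were 576 and 2904 for DKO and KO cells at 4 h, 74 for non-additivity at 0 h and 66 for the KO response. With TMM over all genes they were 57 for non-additivity at 0 h and 672 for the KO response, which was 207 with no filter. Without the libraries of highest top-10 share they were 1347 for DKO cells at 4 h, 1155 for TKO against DKO cells at 4 h, 39 and 41 for non-additivity at 0 and 4 h, and 71 and 209 for the response of DKO and KO cells. With the library sets as a block they were 3290, 3572, 3510 and 2534 for DKO and 972, 1465, 2858 and 8549 for KO cells at 0, 1, 2 and 4 h, 4880 and 4456 for TKO against DKO and 5537 and 1368 against KO cells, 1254 and 363 for non-additivity, and 1222, 3201 and 2632 for the response of DKO, KO and TKO cells. Of the gene lists, 166 tests passed with the preset and 14 with an estimated correlation. The correlation of the DKO and KO effects across genes was 0.708 at 0 h and 0.262, 0.075, 0.21, 0.226, 0.068 and 0.402 with the control libraries divided in 6 ways, and 0.786 at 4 h against 0.653, 0.653, 0.577, 0.623, 0.608 and 0.617, with 0.873 over genes called in either comparison. With the library sets as a block the divided controls gave 0.404, 0.249, 0.294, 0.374, 0.213 and 0.442 at 0 h and 0.645, 0.626, 0.637, 0.605, 0.605 and 0.598 at 4 h.

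Leaving out each library in turn gave 4247 to 5752 genes for WT cells at 1 h, 7803 to 8992 at 2 h and 7905 to 8119 at 4 h. For DKO against WT cells it gave 626 to 1766 at 0 h, 831 to 1524 at 1 h, 1024 to 1929 at 2 h and 432 to 1025 at 4 h. For KO cells it gave 146 to 241 at 0 h, 215 to 363 at 1 h, 588 to 1598 at 2 h and 3582 to 4844 at 4 h. For TKO cells it gave 4964 to 6537, 4075 to 5196, 4874 to 6240 and 6136 to 6600 at 0, 1, 2 and 4 h. TKO against DKO cells ranged over 1216 to 2664 at 0 h and 719 to 1996 at 4 h, and TKO against KO cells over 2064 to 3231 at 0 h and 232 to 354 at 4 h. Non-additivity ranged over 45 to 575 at 0 h and 16 to 42 at 4 h. The difference in response ranged over 58 to 351 in DKO, 100 to 1077 in KO and 820 to 1192 in TKO cells. Libraries that moved a count by more than 1.5 times are named above.

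In all 19 comparisons of 2 groups, only the real 1 of 35 splits of 8 libraries gave as many genes. This lowest possible share cannot exclude chance. The real counts, fitted on these libraries alone, and the highest others were 3522 and 8, 6921 and 5, and 7705 and 9 for WT cells at 1, 2 and 4 h. They were 392 and 147, 719 and 21, 439 and 31, and 1544 and 19 for DKO cells at 0, 1, 2 and 4 h, 94 and 51, 219 and 3, 365 and 58, and 6471 and 0 for KO cells, and 3715 and 11, 3717 and 15, 4281 and 0, and 8209 and 0 for TKO cells. Against DKO cells they were 874 and 40 at 0 h and 2502 and 15 at 4 h, and against KO cells 2395 and 2, and 310 and 4.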

Other observations

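The tests of the scaling, of receptor and keratin genes apart, and of both explanations for the targeted genes were chosen after the result was seen. Genes of other T helper lineages moved in part with loss of Regnase-1 and Roquin. Among Th2 genes 5 of 10 rose and 0 fell (6 and 0 adjusted over the list alone) in KO cells at 4 h (camera adjusted p = 0.024, adjusted p = 0.42 with an estimated correlation), such as Ccr4 (1.41 ± 0.22) and Il4ra (0.94 ± 0.18). Among Th17 genes 7 of 12 rose and 0 fell (7 and 0 adjusted over the list alone) in TKO cells at 1 h (camera adjusted p = 0.0012, adjusted p = 0.24 with an estimated correlation), such as Ahr (1.59 ± 0.30) and Batf (2.74 ± 0.16). Among inhibitory receptor genes 4 of 11 rose and 1 fell (4 and 2 adjusted over the list alone) in TKO cells at 0 h (camera adjusted p = 0.48, adjusted p = 0.83 with an estimated correlation). Among RNA-binding and mRNA decay factors 7 of 21 rose and 1 fell (9 and 1 adjusted over the list alone) in TKO cells at 0 h (camera adjusted p = 0.022, adjusted p = 0.49 with an estimated correlation), with Cnot3 at 0.52 ± 0.11. Among mitochondrially encoded genes 1 of 7 rose and 0 fell (1 and 0 adjusted over the list alone) in TKO cells at 4 h (camera adjusted p = 0.73, adjusted p = 0.86 with an estimated correlation). Among heat shock genes 3 of 11 rose and 0 fell (3 and 0 adjusted over the list alone) in TKO cells at 0 h (camera adjusted p = 0.2, adjusted p = 0.75 with an estimated correlation).

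Markers of other cells did not move alike. In TKO cells at 0 h 3 of 7 B cell genes were higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.58, adjusted p = 0.85 with an estimated correlation). Of 5 myeloid genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.26, adjusted p = 0.61 with an estimated correlation). Of 2 CD8 T cell genes 0 were higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.81, adjusted p = 0.91 with an estimated correlation). Of 2 dendritic cell genes 0 were higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.37, adjusted p = 0.75 with an estimated correlation). The erythroid and platelet list had 1 tested gene, with a log2 change of -0.47 that was not called, and the NK cell and neutrophil lists had 0 tested genes.

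Reads in olfactory and vomeronasal receptor genes were fewer in TKO than in WT cells at each time, and in DKO and KO cells at 4 h (exact permutation p = 0.0286 for each), while keratin genes in sum were not separated. The 165 olfactory and vomeronasal receptor genes and 26 keratin genes together had a median over 16 libraries of 133.8 CPM in WT, 99.3 in DKO, 93.2 in KO and 55.8 in TKO cells. The sums at 4 h are given above. Keratin means in TKO cells were above those in WT cells at 1 h (6.0 ± 1.5 and 5.4 ± 1.6, exact p = 0.6571) and 2 h (5.1 ± 0.7 and 4.2 ± 1.4, exact p = 0.3429). By gene, 156 of 165 receptor and 21 of 26 keratin genes had a lower mean in TKO cells at 4 h. Without the 3 keratin genes of most reads the others held 4.2 ± 0.6 CPM in WT and 1.3 ± 0.2 in TKO cells (exact p = 0.0286). The tables argue against the scaling and against depth as the cause, since the median log2 change of these genes in TKO against WT cells at 4 h was at most -1.37 under the 5 scalings, and the ratio of mean reads, TKO to WT over all times, was 1.014. A background of reads spread over the genome, such as genomic DNA, may be the source and stays open, because with group means removed both families correlated only weakly over the 64 libraries (Pearson's r = 0.292, permutation p = 0.02, and 0.286 without the 2 farthest libraries, with Spearman's rho = 0.286, permutation p = 0.02). A change in the cells themselves was not tested.

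Targeted genes were not lower in every knockout group. Wrong genotype labels could give that. At 1 h all 8 KO or TKO libraries lay below all 8 WT or DKO in Zc3h12a, leaving other times and Roquin loss unchecked. More mRNA of a targeted gene where a partner protein is missing is a candidate explanation for the level of Zc3h12a in DKO cells at 0 h, where its log2 change was 1.78 ± 0.19 (limma adjusted p = 4.5e-10) and the labels name no deletion of it. This remains a hypothesis found and tested on the same data, and transcripts that keep reads outside a deleted exon could also leave gene totals high, which was not tested.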
